A study of Mus musculus with 2 samples.

How the data were processed

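Total RNA from the adrenal glands of 2 adult female B6CASTF1/J mice was used, with 300 ng of RNA per library and ERCC spike-in RNA added, per the labels. The labels give the libraries separate animal numbers and biosamples but the same donor code, so the animals were treated as separate on the strength of the animal numbers. The link to the library protocol names a directional kit. Whether the counting used strand is not given in the sources used here, so values of genes that overlap an antisense partner are uncertain.

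Each library has a gene table and a transcript table derived from an alignment to the transcriptome, and another transcript table derived from the reads and a transcript index. The assembly was mm10 and the annotation GENCODE M21, per the series notes; the programs and their versions are not given in the sources used here. Expected counts are estimates that need not be whole and were not normalized, per the file headers. TPM values were scaled by the authors over all features of a library, tRNAs and spike-ins included. FPKM values were deposited relative to effective length and sequencing depth. The percent of each gene's expression held by a transcript is a deposited column. The deposited lower and upper bounds of TPM describe the error of estimation within 1 library, and the level of these intervals is not given in the file. In the alignment-based tables the effective length is the length minus 100 bases, so 2452 short genes have an effective length of 0 and a TPM of 0. In the index-based tables the difference is 248 bases, which changes TPM most for short RNAs. Both animals carry CAST alleles, and how the counting treated reads that differ from the reference is not given in the sources used here.

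Gene names and coordinates came from GENCODE M21 in the mm10 build, which matched all 55536 gene identifiers. The 26248 tRNA rows, the spike-ins and the phiX174 control were left out of gene counts. Depth was 40453707 and 34319787 expected counts. Shares have 95% Wilson intervals, and the limit of detection was taken as 3 counts. Both cover counting error only.

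Expected counts were rounded for edgeR 4.0.16 (R 4.3.3), which gave TMM factors and, with an intercept-only design and genes kept by its expression filter, the biological coefficient of variation. DESeq2 1.42.0 was the alternative. Log2 ratios are replicate 2 over replicate 1 of TMM-scaled counts with 0.5 added. With 1 library on each side no p-values were computed. A gene was counted as different at an absolute log2 ratio of 1 or more, a mean expected count of 100 or more and deposited TPM intervals that did not overlap. For gene lists, members with a mean count of 10 or more were used, and the median ratio was placed among 10000 random lists whose members were drawn from the 200 genes on each side in rank of mean count. Correlations used log2(TPM + 1), with 1000 bootstrap draws of genes. Spike-ins were set against the 50 protein-coding genes nearest in count. Transcripts were compared in genes at 10 TPM or more, and retained-intron transcripts at a mean count of 20 or more. The remaining steps used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.

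The alternatives tried were other TPM and count limits, other scalings, other pseudocounts, FPKM, the second transcript table, TPM rescaled over protein-coding genes, and each library left out. The groups, tests, alternatives and 34 gene lists were fixed before the data were examined. The genes named in the text were drawn from list members (by default the 5 with the highest TPM, and those at least 2-fold apart), the 15 highest genes, the 10 genes with the largest ratios in each direction, isoforms of steroidogenic and chromaffin genes, and the 5 genes on which the transcript tables differ most. The last were restricted to protein-coding genes at 50 TPM or more, a restriction set after the data had been seen. The comparisons of retained introns and of biotypes were also added then. Further gene lists used in the closing section were written after the first look at the data. At that time 3 members of the further cAMP-responsive list and 8 of the 9 brown-fat-restricted genes had already been seen.

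The scripts were tested on simulated data. With a coefficient of variation of 0.15 over 24129 simulated genes the estimate for replicate 2 over replicate 1 was 0.150. At least a 2-fold ratio was seen for 42% of genes changed 2-fold, 100% of those changed 4-fold and 0.193% of unchanged genes. The criterion of TPM intervals that do not overlap was not part of that simulation. For the gene list step on 17751 genes, 20 of 20 lists of 10 genes shifted by 0.5 on the log2 scale were recovered. Recovery of smaller shifts, such as the -0.17 of the endothelial markers, was not measured.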

Results

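Total RNA was sequenced from the adrenal glands of 2 adult female mice aged 8 to 10 months, both of the B6CASTF1/J strain, the F1 hybrid of C57BL/6J and the wild-derived CAST/Ei line. The adrenal gland has an outer cortex that makes steroid hormones and an inner medulla of chromaffin cells that make catecholamines. Both animals belong to 1 group, so the data describe the tissue and how far 2 animals of the same kind differ. Replicate 1 is animal number 1 and replicate 2 is animal number 3. The gene tables held 40453707 expected counts for replicate 1 and 34319787 for replicate 2, and a count of 3 corresponded to 0.0742 and 0.0874 CPM. Values below are means over the 2 animals with the SD (n = 2) unless an animal is named. Intervals of shares cover counting error only.

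Noncoding transcripts were the most abundant RNAs of the gland. Rn7s1 and Rn7s2, copies of the 7SL RNA of the signal recognition particle, took 40.8% ± 0.826 of TPM (SD, n = 2) and 7.85% ± 0.168 of the expected counts. After the mitochondrial ribosomal RNAs came Rn7sk, a regulator of transcription elongation, at 21206 ± 235 TPM (SD, n = 2). Gm26917, which the annotation classes as a lincRNA, stood at 14551 ± 686 TPM. Rpph1, the RNA of ribonuclease P, stood at 6874 ± 120 TPM and the nuclear lincRNA Malat1 at 5020 ± 1688 TPM. Malat1 was lower in the second transcript table, at 1958 TPM in replicate 1 and 3254 TPM in replicate 2. Rn7s1 (chromosome 12, 69159295 to 69159594) and Rn7s2 (chromosome 12, 69361182 to 69361481) carry equal values in each library, so the share of each copy is uncertain. The pseudogenes Gm10925 (6655 ± 254 TPM) and Gm28437 (5885 ± 30.2 TPM) were also among the 15 highest genes, and reads shared with near-identical sequences make their values uncertain.

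Mitochondrial RNA differed between the animals. All mitochondrial genes together held 11.4% of the counts of replicate 1 (Wilson 95% interval 11.3 to 11.4) and 9.20% of those of replicate 2 (9.19 to 9.21). The ribosomal RNAs mt-Rnr1 and mt-Rnr2 stood at 33365 ± 5859 and 27929 ± 4957 TPM (SD, n = 2), and mt-Co1, a subunit of cytochrome c oxidase, at 8270 ± 546 TPM. Nuclear protein-coding genes held 71.7% of the counts of replicate 1 (71.7 to 71.7) and 72.9% of those of replicate 2 (72.9 to 73.0).

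Genes of steroid synthesis were among the highest nuclear mRNAs. Hsd3b1 (ENSMUSG00000027871.16, chromosome 3, 98852194 to 98859794, mm10), which oxidises pregnenolone to progesterone, stood at 7682 ± 566 TPM (SD, n = 2). Cyp21a1 (chromosome 17, 34801348 to 34804561), the 21-hydroxylase, stood at 6338 ± 81.5 TPM and Star (chromosome 8, 25806555 to 25815982), which carries cholesterol into mitochondria, at 5984 ± 473 TPM. Cyp11b1, the 11-beta-hydroxylase of corticosterone synthesis, reached 3403 ± 458 TPM and Cyp11a1, the side-chain cleavage enzyme, 2594 ± 191 TPM. Of the 16 genes on the steroidogenesis list, 15 reached 1 TPM in both animals and 12 reached 100 TPM. The exception at 1 TPM was Cyp17a1, the 17-hydroxylase, at 0.640 ± 0.212 TPM.

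Markers of the cortical zones were present at different levels. Cyp11b2, the aldosterone synthase of the zona glomerulosa, stood at 169 ± 6.94 TPM (SD, n = 2), and the ratio of Cyp11b1 to Cyp11b2 was 20.1 ± 1.89. In replicates 1 and 2 the second transcript table put Cyp11b2 at 341 and 392 TPM and Cyp11b1 at 2367 and 2840 TPM. The ratio was therefore lower there, and it depends on the table used. The glomerulosa potassium channel Kcnk3 reached 571 ± 30.9 TPM and the angiotensin receptor Agtr1a 92.5 ± 7.06 TPM. All 11 zona glomerulosa markers and all 7 zona fasciculata markers reached 1 TPM in both animals, with list medians of 40.2 ± 3.34 and 843 ± 24.5 TPM. The fasciculata markers are all also on the steroidogenesis or cortex regulator list, and their median is the value of Scarb1. These medians therefore do not measure the zones against each other. Akr1c18, a marker of the X-zone, stood at 359 ± 8.65 TPM. Among regulators of the cortex, Scarb1, the receptor for high-density lipoprotein, reached 843 ± 24.5 TPM, Nr5a1 254 ± 6.02 TPM and the ACTH receptor Mc2r 170 ± 10.4 TPM.

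Transcripts of chromaffin cells spanned a wide range, with a list median of 16.8 ± 0.827 TPM (SD, n = 2). Chga (chromosome 12, 102554969 to 102565028), a granin of secretory vesicles, stood at 763 ± 15.3 TPM, Chgb at 557 ± 85.5 TPM and Scg2 at 355 ± 17.2 TPM. Th, the tyrosine hydroxylase, reached 330 ± 47.0 TPM and Pnmt, which makes adrenaline, 247 ± 0.170 TPM. Of the 22 chromaffin markers, 21 reached 1 TPM in both animals, and Ret stood at 0.805 ± 0.233 TPM.

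Markers of other cell types were measured as well. The endothelial list had a median of 22.7 ± 1.40 TPM (SD, n = 2) with Plvap at 75.0 ± 0.481 TPM, and the capsule and fibroblast list a median of 14.2 ± 4.62 TPM with Dcn at 59.5 ± 18.1 TPM. Macrophage markers had a median of 9.55 ± 0.785 TPM, smooth muscle and pericyte markers 6.20 ± 1.17 TPM, Schwann and sustentacular cell markers 1.05 ± 0.262 TPM, neuron markers 0.785 ± 0.177 TPM and lymphocyte markers 0.205 ± 0.0778 TPM. Adipocyte markers had a median of 92.9 ± 50.7 TPM, with Cfd at 371 ± 165 TPM and Fabp4 at 328 ± 151 TPM. Kidney markers had a median of 0 TPM. Of the 8 pancreas markers, Cela1 alone passed 1 TPM, at 42.4 ± 2.42 TPM. The liver list had a median of 0.870 ± 0.495 TPM and the ovary and oviduct list of 0.140 ± 0.0990 TPM. Of 34 lists, 20 had a median of 10 TPM or more. These levels depend on what TPM is scaled over: rescaled over nuclear protein-coding genes, the steroidogenesis median was 1419 TPM against 505 TPM, and the chromaffin median 47.2 TPM.

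**Figure D1:**
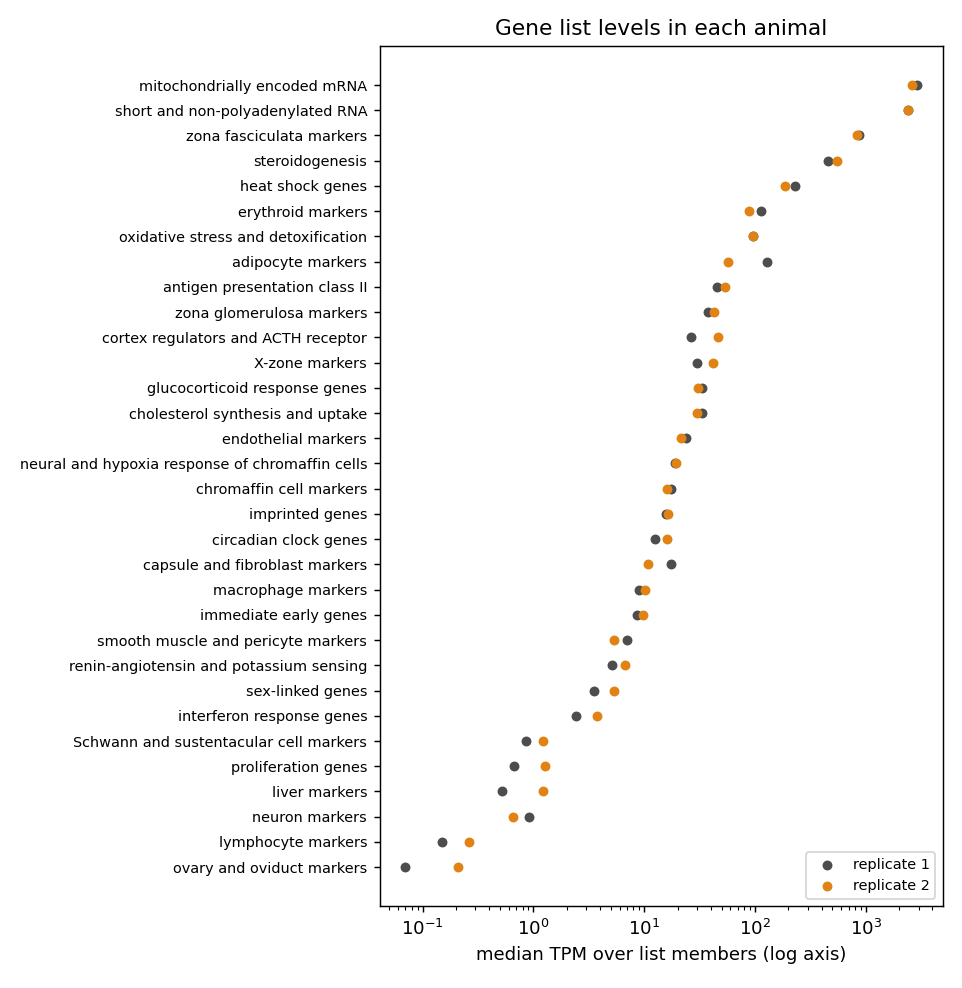
Median TPM over the members of each gene list (log axis), with 1 point per animal; lists with a median of 0 are left out. Zona fasciculata markers lie at 860 and 826 TPM, and adipocyte markers lie at 129 TPM in replicate 1 and 57.1 TPM in replicate 2.

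Lists of cell functions varied in level too. Mitochondrially encoded mRNAs had a median of 2745 ± 210 TPM (SD, n = 2), short and non-polyadenylated RNAs 2413 ± 2.68 TPM, and heat shock genes 208 ± 30.2 TPM. Hba-a1, an alpha-globin gene of the erythroid list, stood at 252 ± 48.4 TPM. Genes of oxidative stress and detoxification had a median of 95.3 ± 0.357 TPM with Sod1, a superoxide dismutase, at 491 ± 0.113 TPM. Cholesterol synthesis and uptake genes had a median of 31.5 ± 2.59 TPM, led by Dhcr7 at 420 ± 15.2 TPM. Imprinted genes had a median of 16.1 ± 0.658 TPM, with Cdkn1c at 341 ± 32.1 TPM, Meg3 at 327 ± 120 TPM and Dlk1 at 310 ± 1.31 TPM. Proliferation genes had a median of 0.970 ± 0.431 TPM. Among sex-linked genes, Xist stood at 53.0 ± 9.96 TPM, and the Y-linked Eif2s3y was at 0 in both animals, which allows up to 0.0742 and 0.0874 CPM.

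In all, 13195 genes reached 1 TPM in both animals, of which 12009 were protein-coding. Replicate 1 alone had 13550 such genes and replicate 2 had 13899. Levels of 1000 TPM or more in both animals were reached by 43 genes.

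The 2 animals differed by less than 2-fold at most genes. Across 13766 genes with a mean of 1 TPM or more, Pearson's correlation of log2(TPM + 1) was 0.979 (bootstrap 95% interval over genes 0.977 to 0.981) and Spearman's 0.978. Genes are not independent replicates, so these values carry no p. After TMM scaling, 97.0% of the genes lay within 2-fold. The biological coefficient of variation, the spread between the libraries beyond counting noise, was 0.152 over 16966 genes. With 1 library per animal it does not part differences between the animals from those of library preparation. The libraries differed by more than sampling noise, with a chi-square of 45.2 per degree of freedom over 12645 genes, so they are not 1 library deposited again. That value does not show that they came from separate animals, which rests on the animal numbers in the labels.

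**Figure D2:**
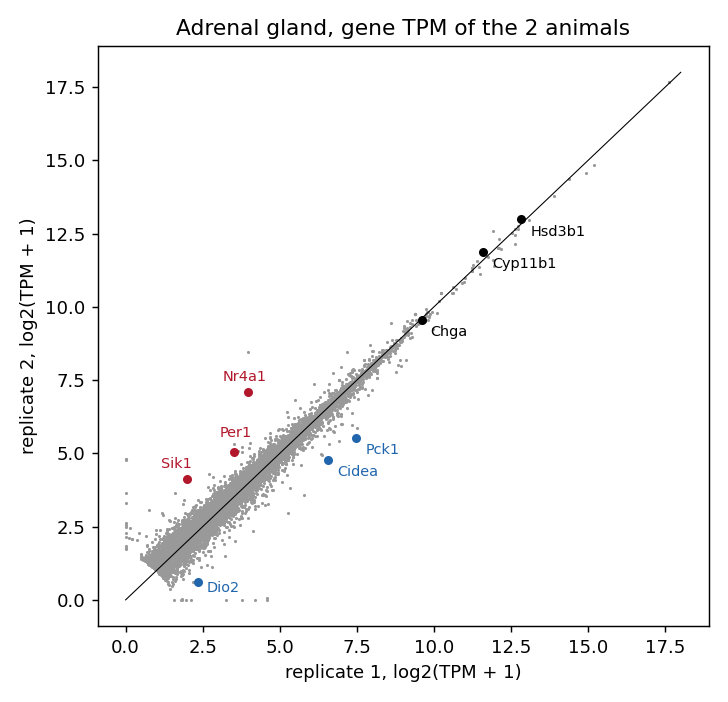
Gene levels of replicate 1 (x axis) and replicate 2 (y axis) as log2(TPM + 1), with 1 point per gene at a mean of 1 TPM or more and a mean expected count of 10 or more, and the line of equality. Hsd3b1, Cyp11b1 and Chga lie near the line, Nr4a1 lies above it (14.8 and 135 TPM) and Pck1 below it (178 and 44.8 TPM).

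Added spike-in RNAs, which carry no biological variation, varied less than genes. The SD of the log2 ratio between the libraries was 0.15 among 24 spike-ins with a mean count of 100 or more, against 0.34 among protein-coding genes matched on count. The spike-ins held 0.226% of the counts of replicate 1 (Wilson 95% interval 0.225 to 0.228) and 0.245% of those of replicate 2 (0.243 to 0.247).

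Nr4a1, Sik1 and Map2k6 were the genes furthest above replicate 1 in replicate 2. Nr4a1 (chromosome 15, 101254269 to 101274795), an orphan nuclear receptor induced by trophic hormones, was at 14.8 TPM in replicate 1 and 135 TPM in replicate 2. On TMM-scaled counts, from which the fold values here were taken, it was 10.8-fold higher. The kinase Sik1 was 5.16-fold higher, Map2k6 5.75-fold, Nr4a2 3.79-fold and the clock gene Per1 3.27-fold. The plasma protein genes A2m, Apob and Alb were 4.57-fold, 3.35-fold and 3.14-fold higher, and the mitochondrial carrier Slc25a25 3.17-fold. In the other direction, Dio2, the deiodinase that activates thyroid hormone, was 7.93-fold lower in replicate 2, Pdk4 4.34-fold, Fabp3 4.28-fold, Pck1 4.20-fold and Cidea 3.77-fold. Cd163, a macrophage scavenger receptor, was 3.60-fold lower.

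Of 12645 genes with a mean expected count of 100 or more, 151 differed by at least 2-fold with deposited TPM intervals that did not overlap, 63 higher and 88 lower in replicate 2. On TPM as deposited the split turned, with 120 higher and 67 lower, as it did with a mean expected count of 10 or more, where 532 genes differed, 373 higher and 159 lower. Among the 63 higher genes 43 were protein-coding, and among the 88 lower genes 87 were. With 1 library on each side these differences have no replicate check. The largest ratio, that of Gm28539, rests on 3.25 expected counts in replicate 2, and its model overlaps other genes.

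**Figure D3:**
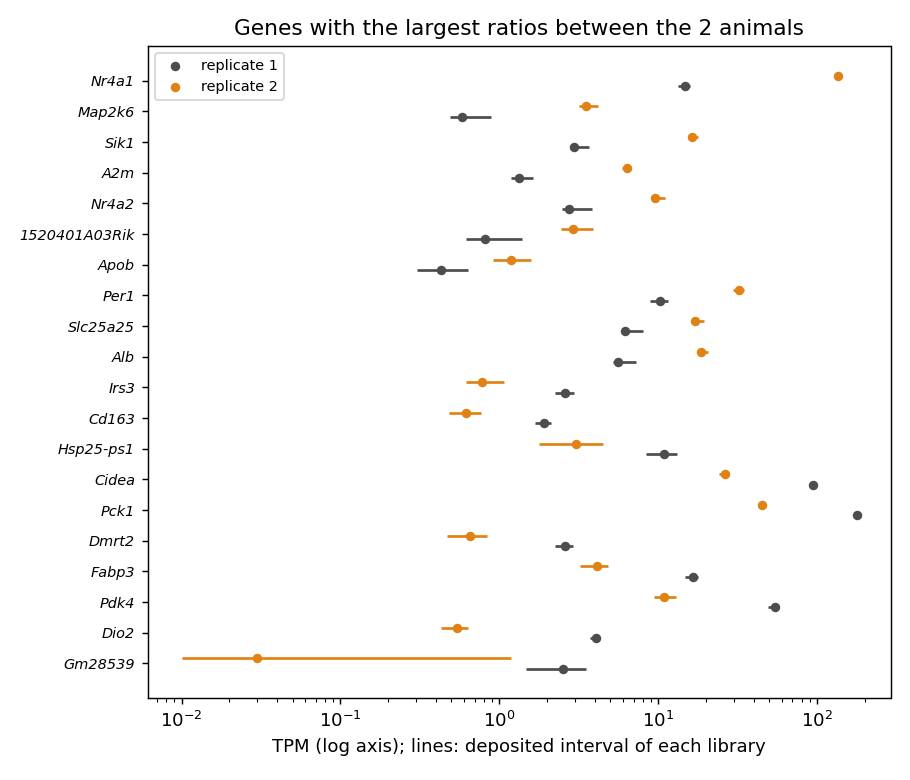
TPM (log axis) of the 10 genes with the largest ratios in each direction, in replicate 1 and replicate 2, with lines for the deposited interval of each library. Values and bounds under 0.01 TPM are drawn at 0.01; Nr4a1 goes from 14.8 to 135 TPM and Dio2 from 4.04 to 0.540 TPM.

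Adipocyte markers were lower in replicate 2 as a group. All 10 members lay below 0, with a median log2 ratio of -1.04, under every one of 10000 random lists matched on mean expression (percentile 0). Ucp1, the uncoupling protein of brown fat, had a log2 ratio of -1.48, Fabp4 of -1.07 and the adipokine gene Adipoq of -1.05, whereas the leptin gene Lep had -0.01. Capsule and fibroblast markers had a median of -0.50 (percentile 0) with Col3a1 at -1.09, and smooth muscle and pericyte markers a median of -0.55 (percentile 0) with Acta2 at -1.07. Erythroid markers had a median of -0.48 (percentile 0.15), neuron markers -0.41 (percentile 1.58) and endothelial markers -0.17 (percentile 1.23). Under 3 neuron markers kept a mean count of 100 or more, so that list could not be placed at that limit.

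Heat shock genes were lower in replicate 2 as well. All 9 members lay below 0, with a median of -0.76 (percentile 0). The inducible chaperone Hspa1b had a log2 ratio of -1.69, Hsph1 -1.31, Hspa1a -1.15 and the constitutive chaperone Hspa8 -0.88, while the endoplasmic reticulum chaperone Hspa5 had -0.02.

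Chromaffin markers had a median log2 ratio of -0.19 (percentile 0.09) with 21 of 22 members below 0, among them Chgb at -0.41 and Th at -0.38. Cholesterol synthesis and uptake genes had -0.19 (percentile 0.14), mitochondrially encoded mRNAs -0.22 (percentile 0.49) and genes of the neural and hypoxia response of chromaffin cells -0.26 (percentile 0.41). Steroidogenesis genes had a median of -0.02 (percentile 90.2), zona glomerulosa markers 0.02 (percentile 92.5) and zona fasciculata markers 0.03 (percentile 95.9), all inside the range of random lists. Each zone list shares members with the steroidogenesis list, so these are not separate results. Akr1b7, an aldo-keto reductase of the fasciculata, had 0.74.

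X-zone markers and liver markers lay above the random range in replicate 2 in the gene table. The 3 X-zone markers had a median of 0.36 (percentile 99.5), with Thrb at 0.45 and Pik3c2g at 0.36, while Akr1c18, the most abundant of them, had -0.04 with intervals that overlapped. The 6 liver markers measured had a median of 1.23 (percentile 99.96), with Alb at 1.65. Under 3 of them kept a mean count of 100 or more, so the list could not be placed at that limit. Immediate early genes had a median of -0.1770 at percentile 2.5, just below the interpolated lower bound of -0.1768, with Fos at -1.04 beside Nr4a1 at 3.43. Circadian clock genes had a median of -0.01 (percentile 76.8), glucocorticoid response genes -0.03 (percentile 63.7) and proliferation genes 0.24 (percentile 89.2). In the second transcript table proliferation genes had 0.45 (percentile 99.1) and sex-linked genes 0.23 (percentile 98.0), both above the range there.

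Of 32 lists with 3 or more members measured, 13 had a percentile in the outer 2.5% on either side of their random lists. Judged by the interpolated bounds of the range, 14 lay outside, the immediate early genes being added. These differences have no replicate check. In simulated data 13 of 200 lists with no shift also had such a percentile. The random lists were drawn gene by gene, whereas members of a real list can vary together. The simulated count is therefore not an error rate for the real lists.

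**Figure D4:**
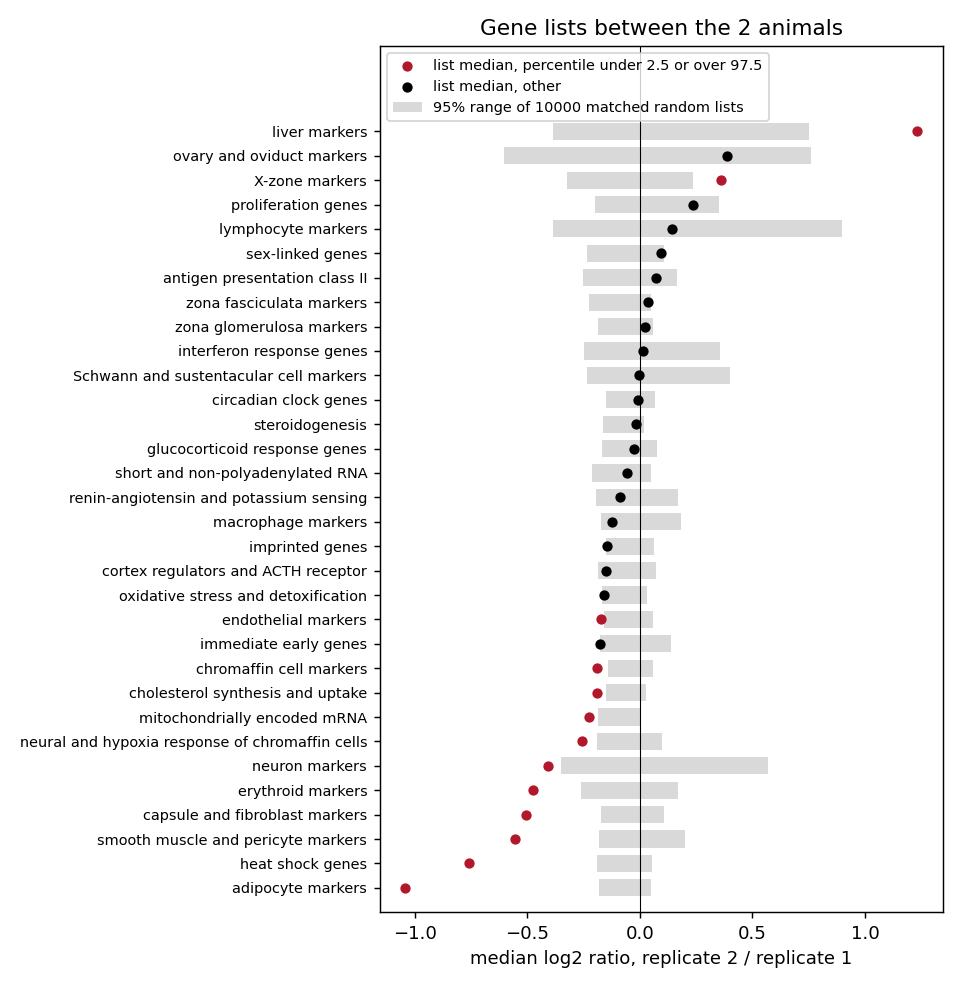
Median log2 ratio of replicate 2 over replicate 1 for each gene list (points), with the 95% range of 10000 random lists matched on mean expression (grey bars). Adipocyte markers at -1.04 and heat shock genes at -0.76 lie furthest to the left, and liver markers at 1.23 furthest to the right.

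Among noncoding RNAs, Malat1 had a log2 ratio of 0.60, Neat1, the RNA of paraspeckles, 1.34 and Meg3 0.73. Gm26917, the most abundant gene annotated as a lincRNA, had -0.18. These genes were not tested as a group. Within 4625 genes, transcripts annotated as retained introns had a median log2 ratio 0.47 above that of the coding transcripts of the same gene (bootstrap 95% interval over genes 0.44 to 0.48). Over 11902 protein-coding genes the median was -0.03, and over 93 lincRNAs it was 0.16. The class medians lay between -0.13, over 253 processed pseudogenes, and 0.60, over 69 genes of the annotation class TEC. Whether these class differences bear on the gene and list differences above was not tested.

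Steroidogenic genes kept 1 main transcript in both animals and both transcript tables, in 11 of 11 genes with several annotated transcripts. Cyp11a1-201 held 98.8% ± 0.277 of the gene's TPM (SD, n = 2) in the table made from alignments and 86.6% ± 1.19 in the table made from an index. Star-202 held 50.7% ± 0.585 and 55.8% ± 0.373. Of the chromaffin genes 8 of 10 did so, with Th-201 at 99.96% ± 0.0501 and 88.4% ± 1.26. For Ddc, the decarboxylase of dopamine synthesis, the first table put Ddc-202 highest at 51.6% ± 9.83 and the second put Ddc-210 highest at 91.7% ± 2.03.

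Over all genes at 10 TPM or more with several transcripts, the highest transcript was the same in both animals for 5530 of 6001 genes, or 92.2% (Wilson 95% interval 91.4 to 92.8), and in the second table for 5033 of 5570, or 90.4% (89.6 to 91.1). The 2 tables of 1 library named the same transcript in 80.1% ± 0.709 of genes (SD, n = 2). Their Pearson correlation across 141767 transcripts was 0.847 in each library. The mitochondrial gene mt-Atp8 stood at 1472 ± 96.8 TPM in the first table and at 5.09 and 0.995 TPM in the second, while the ribosomal protein gene Rpl27 stood at 16.7 and 22.4 TPM in the first and 212 and 215 TPM in the second. Rpl10-ps3 and AC149090.1 were listed at 0 in the second table.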

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

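No test of an explanation was run for the counts in this part. Reads of phiX174, a sequencing control that no comparison uses, were counted in both libraries, with 116 expected counts in replicate 1 and 78 in replicate 2, above the 3 counts taken as the limit of detection. The tRNA rows, left out of the gene comparisons, held 6.75 expected counts in replicate 2.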

How the results depend on the processing

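The rescaled intervals and the spike-in limit of 1000 counts were chosen after the data were seen. Pearson's correlation between the animals was 0.958 with a pseudocount of 0.1, 0.993 with no filter, 0.985 for protein-coding genes and 0.984 from the second transcript table. The coefficient of variation was 0.173 with no filter and 0.142 for protein-coding genes. The DESeq2 value of 0.159 is the median of a trend fitted over mean count, for which edgeR gave 0.144. With a mean count of 10 or more, 532 genes differed (373 higher, 159 lower) against 151, where more low-count genes enter; the other settings gave 149 to 187. The spike-in SD was 0.34 at a mean count of 10 or more, against 0.56 for genes matched on count, and 0.036 at 1000 or more, against 0.23. The correlation of the transcript tables was 0.830 with a pseudocount of 0.1 and 0.657 among transcripts at 1 TPM or more in either. The highest transcript was the same in both animals for 88.2% of genes at 1 TPM or more, 90.4% in the second table and 99.4% where it exceeded the next by 1.5 times. The causes of these shifts were not tested. Genes detected in both animals numbered 18721 at a limit of 0.1 TPM and 9231 at 5 TPM, against 13195 at 1 TPM. With the deposited posterior-mean TPM they numbered 15902. Without replicate 1 or 2, detected genes numbered 13550 to 13899, lists at 10 TPM or more 20 to 21, the table correlation stayed at 0.847 and the shared highest transcript at 79.6 to 80.6%. The 13 lists called by percentile among random lists were also called with the second table, which gave 17 by adding proliferation (0.45), sex-linked (0.23), immediate early (-0.18) and imprinted genes (-0.15); at a mean count of 100 or more 12 were, 11 of them among the 13 and the other imprinted genes (-0.16), while neuron and liver markers kept under 3 members. DESeq2 and spike-in scaling shift every gene alike and so cannot change a place among random lists. No called list changed sign. TPM rescaled over nuclear protein-coding genes put 22 lists at 10 TPM or more. This rescaling multiplies all such genes of a library by 1 factor and sets other genes to 0. It thereby moved 32 of 34 list medians by more than the spread between the animals, which is a matter of arithmetic. The second transcript table moved 17 of 34 by more than that spread and left 20 lists at 10 TPM or more. No paired analysis was possible because there is only 1 group. Depth limits statements on genes near 3 counts.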

Other observations

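The tests of one adipose mixture, of adipose tissue as the source of heat shock transcripts, of cAMP-responsive genes, of circadian phase and of the quantification method were chosen after the results were seen; the further adipocyte and heat shock lists and the intronless test were written before their values were seen. Cirbp, a cold-inducible RNA-binding protein gene chosen after its values were seen, stood at 15.2 TPM in replicate 1 and 40.2 TPM in replicate 2, and Rbm3, of the same class, had a log2 ratio of 0.45. No biological explanation could be tested against a group, since both animals belong to 1 group.

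Adipocyte genes were lower in replicate 2. The choice between the 2 quantifications does not account for this, as the list median was -1.08 in the second transcript table. Both quantifications rest on the same libraries, so an error that they share is not excluded. As a hypothesis, less adipose tissue may have been attached to the gland of replicate 2: 25 further adipocyte genes had a median of -0.77, below all matched random lists, with Fasn at -0.84 and Lpl at -1.04, although the cortex itself may express part of them. Brown-fat-restricted genes differed from pan-adipocyte genes by -0.59 (bootstrap 95% interval -1.17 to -0.40). One adipose mixture in different shares would not give this difference if the rest of the gland expressed none of these genes. Expression in the rest of the gland was not measured, so the difference does not decide whether 1 mixture was present. Also, 8 of the 9 brown-fat-restricted genes had been seen beforehand, most of them because they differed. The question of 1 mixture was left open by a rule set after the value was seen. A change within the fat cells of either animal was not tested.

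Heat shock genes were lower in replicate 2. Over 235 intronless protein-coding genes the median was -0.14, below the -0.03 over 11902 protein-coding genes. The heat shock median was -0.76, so a general loss of intronless transcripts of that size is argued against. A smaller loss is not excluded. Such a loss could act only on heat shock genes without introns, so the test does not bear on the others. Lower heat shock factor activity is a hypothesis that the data are consistent with, since 16 further targets had a median of -0.47, below all matched random lists, with Dnaja1 at -0.70 and Bag3 at -0.63. Attached adipose tissue cannot be told apart from it in bulk tissue. The heat shock genes lost 2.22 times the TPM that Ucp1, Adipoq and Fabp4 lost together, which was under a limit set after the results were seen. How much heat shock RNA the adipose tissue held was not measured, so this ratio does not decide the question.

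Nr4a1, Sik1 and Per1 were higher in replicate 2. The choice between the 2 quantifications as the cause is argued against by an Nr4a1 log2 ratio of 3.32 in the second table. An error shared by both is not excluded. A shift of circadian phase by hours stays open. Among 11 other clock genes with a mean count of 100 or more the largest absolute ratio was 0.49, that of Per3. The 13 clock genes without Per1, Bhlhe40 (0.43) and Bhlhe41 (0.02) had a median of -0.17 (percentile 2.14). With these genes included, the 16 clock genes had a median of -0.01 (percentile 76.8), 8 higher and 8 lower. The place among random lists therefore depends on which genes are left out. A general rise of cAMP-responsive genes also stays open: 19 further genes had a median of -0.076 (bootstrap 95% interval -0.56 to 0.22), 0 of them at least 2-fold higher and 3 at least 2-fold lower, and the 16 not seen before the list was written had -0.11. The list of 13 clock genes and that of 19 further cAMP-responsive genes leave out the genes that prompted the question. No member of either list was at least 2-fold higher in replicate 2, so a rise as large as that of Per1 was absent among them. The cause for Nr4a1, Sik1 and Per1 themselves is not tested by other genes, so neither explanation is excluded for them. This reading was settled after the values were seen. Under the limits first written both lists would have been taken as evidence against. An acute hormonal difference between the animals was not tested.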
